A study of Caenorhabditis elegans with 2 samples.

How the data were processed

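Binding of eGFP-tagged FOS-1 was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole L1 larvae of Caenorhabditis elegans, in 2 biological replicates of 1 group taken from separate biosamples of the same strain, per the labels. The labels give a size range of 150 to 350 for the libraries without a unit. No group of control samples was part of the comparison, and mock immunoprecipitations were not used here.

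The deposited files are 8 lists of regions in narrowPeak format, 4 for each of the genome builds ce10 and ce11. Each build has a list for each replicate, a pooled list and a list of peaks retained by the irreproducible discovery rate (IDR) procedure, which is meant to weigh how alike peaks rank in both replicates. Per the deposited text files, each replicate's list was made from that replicate's alignments and a control file, the pooled list from the alignments of both replicates and the same control file, and the IDR list from the pooled list and both replicate lists. The replicate and pooled lists are described there as peaks and background, so most of their entries are weak. The aligner, the peak caller, the IDR threshold and the duplicate filter are not given in the sources used here. The same control file entered both replicates' lists, so any bias of the control is shared by them.

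The signal value of each entry is the authors' own, as deposited, and its scaling is not stated. The lists differ in scale (median signal 9.60 in replicate 1, 8.00 in replicate 2 and 17.1 in the pooled list), so entries were compared between lists by overlap and rank, not by value. The deposited −log10 q value of each entry is capped: all 1895 IDR peaks in ce11 carry the top value of the pooled list, 3.63, so the signal value was used to rank peaks. Read depth per replicate is unknown, because the lists hold no read counts. Intervals of shares given here are 95% Clopper-Pearson intervals over peaks or genes and cover counting error only; neighbouring peaks and genes are not independent. For shares in each replicate alone, the 1895 entries with the highest signal in that replicate's list were used, and their mean is given with its SD (n = 2).

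Genes and sequence came from WBcel235, the assembly named ce11 in the files, with Ensembl release 115 gene models (19985 protein-coding genes). None of the entries of the ce11 lists ended past the end of its chromosome in this assembly (0 entries). The ce10 lists were compared only with each other. A promoter window ran from 1000 bp upstream to 200 bp downstream of the annotated 5' end of a protein-coding gene, and a peak was placed by its summit. Overlap meant at least 1 bp in common, computed with code whose counts of IDR peaks in each replicate list were checked against bedtools 2.31.1. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

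Overlaps with replicate lists were compared with 100 circular shifts of the peaks within chromosomes (one-sided permutation test, smallest possible p = 0.0099), and promoter shares with 1000 shifts (two-sided, smallest possible p = 0.0020). Motifs were searched on both strands within 50 bp of each summit and in a window of the same width placed 400 bp to a random side, with exact McNemar tests, two-sided, and Benjamini-Hochberg adjustment over 8 motifs. The motifs were TGASTCA (S is C or G; the AP-1 site of Fos-Jun factors), a scrambled form TCASTGA, TGACGTCA, TGATAA, TGTTTAC, CACGTG, GGGCGG and GAGAGAG. For 23 gene lists, genes with a summit in their promoter window were compared with all other protein-coding genes by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment; symbols not found in the annotation were left out (5 of all list entries). The share of peaks on X was tested with an exact binomial test, and the trend of AP-1 sites with signal by a permutation test with 100000 resamples. Entries within 20 kb of a gene were ranked among windows of the same size stepped by 5000 bp. The McNemar, Fisher's and binomial tests treat peaks or genes as independent, so their p-values may be too small.

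The tests, gene lists, motifs and most alternatives were fixed before the data were examined. Genes were named by a rule fixed at that time: fos-1, jun-1 and unc-119; the gene with the nearest 5' end for the 10 IDR peaks of highest signal; and, in lists that passed the adjustment and in the first 4 lists, up to 4 members with the highest promoter peak signal, with a member lacking a peak for lists without any. The mitochondrial genes among them were named from the RefSeq table by coordinates. Genes outside this rule are named as chosen after their values were seen. Alternatives covered the overlap rule, the number of top entries, the promoter window, the motif window and flank, the higher-signal part of the IDR list, each replicate alone, the background of genes and the ce10 lists; restricting to nuclear chromosomes and leaving out ribosomal protein genes were added after seeing the data.

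The code was tested on simulated peaks. In 20 sets of 1895 randomly placed peaks, 2 gene-list calls were made in all and 0 sets had an AP-1 p-value below 0.05. These peaks were placed evenly over the nuclear chromosomes, whereas 60% of the real peaks lay at promoters. False calls among peaks gathered at promoters were therefore not assessed. A motif planted in 10% of the peaks was recovered in 10.6% of summit windows, against 0.840% of flanks.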

Results

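FOS-1 is the worm member of the Fos family of basic leucine zipper (bZIP) transcription factors, which bind DNA with a partner such as Jun. Its binding was mapped in 2 biological replicates of whole L1 larvae, the first larval stage, of strain OP304, in which an integrated transgene (wgIs304) carries fos-1 tagged with eGFP. In build ce11 the authors' IDR list held 1895 peaks, with a median width of 340 bp, on 615 kb of the genome. The pooled list held 20363 entries, the list of replicate 1 held 29801 and that of replicate 2 held 23483. The IDR list was made up of exactly the 1895 entries of highest signal in the pooled list. Read depth was unknown, so a missing peak was read as not listed and not as absence of binding.

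The strongest sites were shared by the replicates. The peak upstream of cebp-1, a bZIP factor of the C/EBP family (X:1454429-1454789, summit 742 bp upstream of the 5' end, intergenic), had the highest signal of the nuclear genome, 688 in the pooled list, and ranked 2 in both replicates. A peak 172 bp upstream of cdc-48.1, which encodes an AAA ATPase of protein quality control (II:10563458-10563685), had a signal of 493 and ranked 4 in replicate 1 and 6 in replicate 2. The peak 86 bp upstream of jun-1, the gene of the Jun-type partner (II:9112892-9113224), had a signal of 378 and ranked 10 and 21, and that of tag-325 (III:4796119-4796368, 597 bp upstream) had a signal of 377 and ranked 21 and 11. A pair of the 10 highest peaks lay far from any protein-coding 5' end on X: X:11093955-11094348, 4018 bp from the 5' end of W02H3.3 (signal 396), and X:13700662-13700994, 6053 bp from that of K02D3.1 (signal 379). The remaining 4 were mitochondrial and had their nearest 5' ends at ND5 (signal 1038), COX3 (621), CYTB (397) and ND2 (377), genes of respiratory chain subunits. The mitochondrial genome, of 13794 bp, carried 26 peaks, or 1885 per Mb, against 12.4 to 24.8 per Mb on nuclear chromosomes. Whether the mitochondrial peaks reflect binding of FOS-1 was not tested.

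Of the 1895 IDR peaks, 1879 (99.2%) overlapped an entry in both replicate lists, against a mean of 7.66% and a maximum of 9.39% over shifted placements (one-sided permutation p = 0.0099, the smallest that 100 shifts can give). Among the 1895 highest-signal entries of each replicate, 68.8% of those of replicate 1 overlapped those of replicate 2, and 68.4% the other way, against 2.35% for shifted placements (permutation p = 0.0099). Across the 1879 shared peaks, Spearman's rho of the replicates' signals was 0.608 and Pearson's r of log2 signals was 0.73; peaks are not independent replicates, so no p is given. The IDR list was built from these same lists, and both replicates shared a control file, which limits what the overlap shows. When only each replicate's 1895 top entries counted, 1288 of the IDR peaks were found in both.

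**Figure D1:**
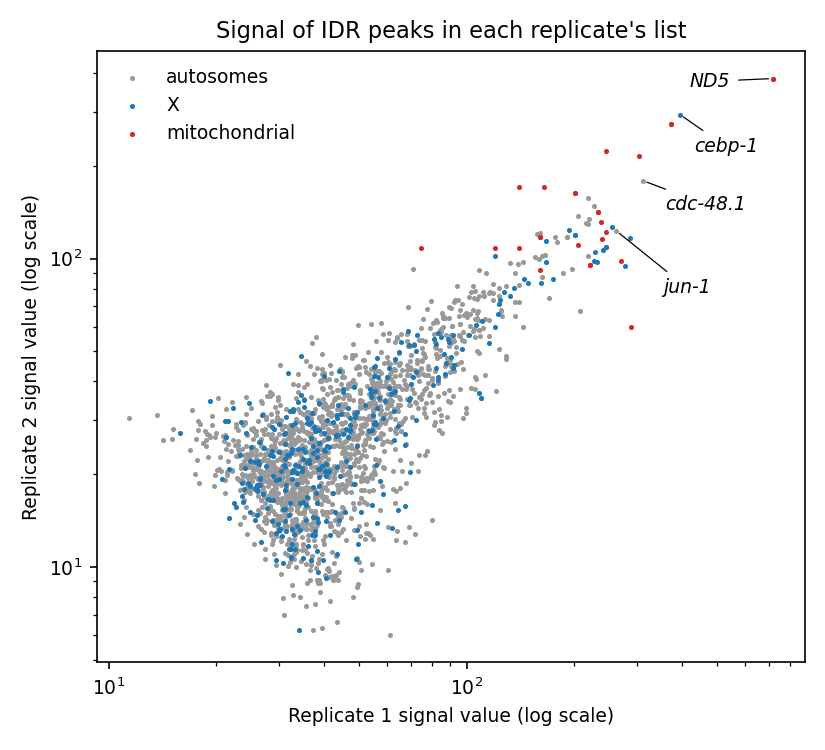
Signal values of the 1879 IDR peaks found in both replicate lists (each point is a peak; log axes, replicate 1 across and replicate 2 up; colours give autosomes, X and the mitochondrial genome). Spearman's rho is 0.608, and cebp-1, cdc-48.1, jun-1 and ND5 lie in the upper right.

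Peaks lay mainly at promoters. Summits of 1137 IDR peaks (60%, interval 57.8 to 62.2) fell in the promoter window of a protein-coding gene, while shifted placements gave 21.9% ± 0.956 (SD of 1000 shifts; two-sided permutation p = 0.0020, the smallest they can give). The top entries of each replicate alone gave 57.9% ± 0.187 (SD, n = 2). Of the other summits, 413 (21.8%) were intergenic, 310 in introns, 15 in 5' UTRs, 13 (0.686%) in coding exons and 7 in 3' UTRs. The 10181 entries of lowest signal in the pooled list differed: 23.8% were at promoters (two-sided Fisher's exact p = 3.16e-202), 33.6% in introns and 10.8% in coding exons. The share of IDR peaks at promoters was lowest on X, at 46.2% (interval 40.8 to 51.8), and ranged from 57.9% on IV to 66.3% on II among autosomes. X holds 13.7% of protein-coding genes on 17.7% of the nuclear genome, and no share expected for each chromosome was computed. On the mitochondrial genome, of 13794 bp with 12 protein-coding genes, 21 of 26 summits were counted as at promoters. With nuclear peaks only, the share was 59.7%.

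The AP-1 site TGASTCA was found within 50 bp of 72 summits, or 3.80% (interval 2.98 to 4.76), including that of cebp-1 but not those of jun-1, cdc-48.1 or tag-325. Flanks of the same peaks held it in 0.95% (interval 0.564 to 1.5), a ratio of 4.0 (exact McNemar test, two-sided, adjusted p = 2.06e-08). The top entries of the replicates gave 3.59% and 3.54%, so both were above the flank level. The 10181 entries of lowest signal in the pooled list gave 1.13%. The scrambled motif TCASTGA did not pass (1.42% of summits, 1.58% of flanks, exact adjusted p = 0.791). GAGAGAG, a GA repeat, was the most frequent motif, at 307 summits (16%) and in 1.53% of flanks (exact adjusted p = 4.87e-62; 14.8% and 15.4% in the replicates). The E-box CACGTG (3.80% against 1.32%, exact adjusted p = 1.31e-06) and the GC-box GGGCGG (4.80% against 1.74%, adjusted p = 1.71e-07) were also more frequent at summits. TGATAA, the site of GATA factors, was less frequent at summits (4.96%) than in flanks (9.50%, exact adjusted p = 1.71e-07), and the forkhead site TGTTTAC did not pass the adjustment (1.95% against 1.16%, adjusted p = 0.0717). The cAMP-response site TGACGTCA was in 0.95% of summits and 0.106% of flanks (exact adjusted p = 0.000537), a call that was lost with flanks 1000 bp away (adjusted p = 0.728), with a window of 25 bp (0.0514), with the whole interval (0.427) and in replicate 2 alone (0.193). The call for CACGTG was lost in the 947 IDR peaks of higher signal (exact adjusted p = 0.0721), and TGTTTAC passed with flanks 1000 bp away (0.0297) and in each replicate alone (0.0118 and 0.000613).

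**Figure D2:**
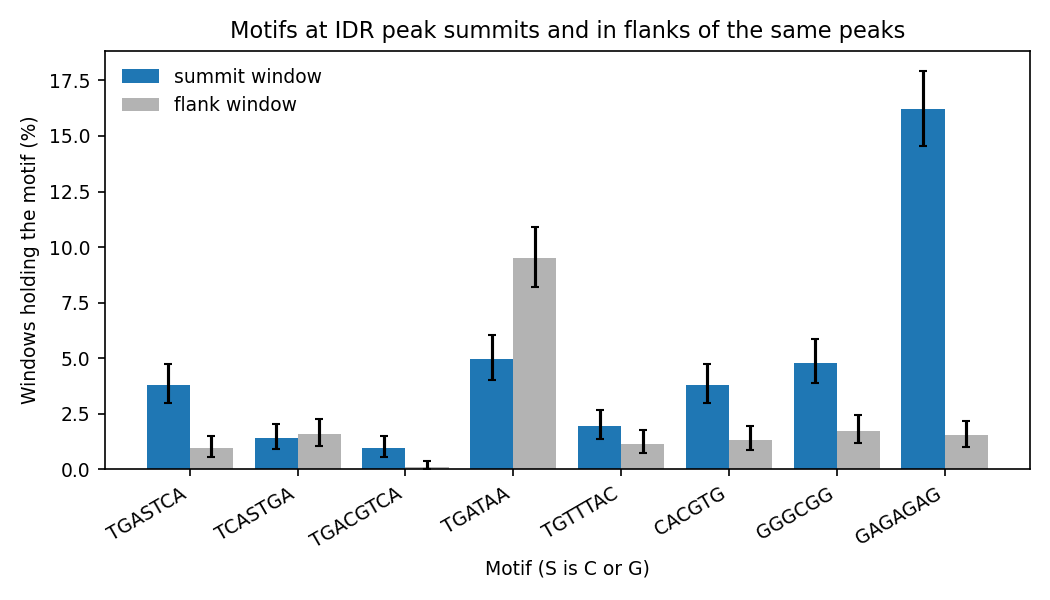
Percent of summit windows (blue) and flank windows (grey) of the 1895 IDR peaks that hold each of 8 motifs, with 95% Clopper-Pearson intervals as bars. GAGAGAG reaches 16% at summits against 1.53% in flanks, and TGASTCA 3.80% against 0.95%.

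Within the IDR peaks, no trend of AP-1 sites with signal was detected. With the peaks split by signal into groups of 379, the site was present in 4.49% of the group with the highest signal, 2.64% of the middle group and 4.75% of the group with the lowest. Spearman's rho of signal with presence of the site was -0.0160 (two-sided permutation p = 0.485). The 10181 entries of lowest signal in the pooled list held the site in 1.13%, against 3.80% of IDR peaks (two-sided Fisher's exact p = 3.37e-14). Pooled entries ranked between these and the IDR peaks were not compared.

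Promoter windows of 1529 protein-coding genes (7.65%) held a summit, and 6 of the 23 gene lists differed from other genes. Ribosomal protein genes stood out, with 62 of 78 (79.5%, interval 68.8 to 87.8; 7.37% of other genes; Fisher's exact test, two-sided, adjusted p = 2.29e-53), and 76.9% and 75.6% in the replicates alone. With each peak given only to its nearest gene within 2000 bp, the share was 48.7% (exact adjusted p = 1.16e-22). Their highest peaks were at rpl-3 (III:3867454-3867708, signal 374), rpl-20 (IV:4749946-4750169, 357), rpl-35 (III:7854567-7854810, 323) and rps-12 (III:5679033-5679230, 295), all intergenic and 156 to 454 bp upstream of the gene. The rpl-20 peak was nearer the 5' end of Y17G9B.5 on the other strand (175 bp, against 287 bp), and the rps-12 peak nearer that of ska-3 (137 bp, against 156 bp). The bZIP factors, the family of FOS-1 itself, had peaks at 8 of 27 genes (29.6%, interval 13.8 to 50.2, Fisher's exact adjusted p = 0.00315). Besides cebp-1 and jun-1 these included xbp-1, a factor of the unfolded protein response (III:4193613-4193952, signal 170, 26 bp upstream), and zip-4 (I:3266586-3266925, signal 107, in the 5' UTR). The bZIP call rested on replicate 1: the top entries of replicate 2 alone gave 18.5% (exact adjusted p = 0.132).

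Chemoreceptor, innate immunity, detoxification and neuropeptide genes had promoter peaks less often than other genes. Chemoreceptor genes had promoter summits at 5 of 1293 (0.387%, interval 0.126 to 0.9; 8.15% of other genes; Fisher's exact adjusted p = 1.91e-37), with the highest at sri-5 (signal 92.5), srh-16 (69.6), sre-23 (53.9) and srh-2 (49.5, a peak nearer the 5' end of icl-1). Innate immunity effectors had 1 of 314 (0.318%, exact adjusted p = 4.45e-09), the C-type lectin gene clec-126 (II:3519047-3519386, signal 65.6). Detoxification enzymes had 3 of 185 (1.62%, exact adjusted p = 0.00315), namely gst-27 (signal 111), cyp-13A2 (54.8) and ugt-20 (49.9), and neuropeptide and insulin genes had 2 of 140 (1.43%, exact adjusted p = 0.00796), ins-39 (192) and ins-14 (53.3). All 4 shares were below those of other genes in both replicates alone: 0.309% and 0.464% for chemoreceptors, 0.318% in each for immunity effectors, 2.70% and 1.08% for detoxification, 1.43% and 0.714% for neuropeptides. With each peak given to its nearest gene within 2000 bp, the calls for detoxification enzymes (exact adjusted p = 0.0730) and neuropeptides (0.277) were lost, and the latter also in the 947 peaks of higher signal (0.0926).

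FOS-1-linked genes, MAP kinases, basement membrane genes and vacuolar ATPase subunits did not pass the adjustment. Of 12 genes linked to FOS-1 in earlier worm genetics, which include its anchor cell invasion targets, only jun-1 had a promoter summit (8.33%, interval 0.211 to 38.5, Fisher's exact adjusted p = 0.745). The list also holds fos-1 itself, and jun-1 is there as its partner gene. Whole L1 larvae may not show binding limited to other stages or to few cells, so these targets are not called unbound. MAP kinase signalling had 2 of 25 (8.0%, exact adjusted p = 0.824), the JNK-like kinase gene kgb-1 (IV:410379-410718, signal 92.2, nearer the 5' end of T07A9.12) and the p38 kinase gene pmk-2 (IV:8142946-8143285, signal 51.4). The pmk-2 peak ranked 825 in replicate 1 but 8573 in replicate 2, whose top entries alone lacked it and gave 4.0% for the list. Basement membrane and matrix remodelling genes, among them the collagen IV gene emb-9, had 0 of 27 (interval up to 12.8%, exact adjusted p = 0.405). Vacuolar ATPase subunits had 5 of 20 (25%, exact adjusted p = 0.0503), a list that passed with a window of 2000 bp upstream (0.0340), in replicate 1 alone (0.0427) and in replicate 2 alone (0.00958). It also passed with 1 gene per cluster of 5' ends (exact adjusted p = 0.0201), in the 947 peaks of higher signal (0.0318) and without ribosomal protein genes (0.0482), but not with nearest genes (0.132), the narrower promoter window (0.10) or named genes as background (0.0877).

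The other lists also missed the threshold. Heat shock and oxidative stress genes had peaks at 6 of 36 (exact adjusted p = 0.137), cell adhesion genes at 4 of 25 (0.250), neuron markers at 5 of 39 (0.388), core histones at 6 of 72 (0.901), cuticle collagens at 7 of 175 (0.194), homeobox genes at 2 of 92 (0.135) and nuclear hormone receptors at 15 of 269 (0.405). Tissue markers had 2 of 27 for body wall muscle (1.0), 1 of 33 for intestine (0.656), 1 of 15 for the excretory system (1.0), 1 of 38 for germline (0.522), 0 of 33 for epidermis (0.337) and 0 of 18 for pharynx (0.532). These are adjusted p-values of two-sided Fisher's exact tests. The shorter lists leave wide intervals, with upper limits of 18.5% for pharynx and 36.1% for cell adhesion genes. Single alternatives brought 4 of these lists past the threshold: heat shock genes, above other genes, with 1 gene per cluster of 5' ends (0.0174); neuron markers, above, with nearest genes (0.0216); cuticle collagens, below, with 2000 bp upstream (0.0431) and among named genes (0.0217); and homeobox genes, below, among named genes (0.0332). Their highest adjusted p over all alternatives was 1.0, 1.0, 0.826 and 0.480.

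**Figure D3:**
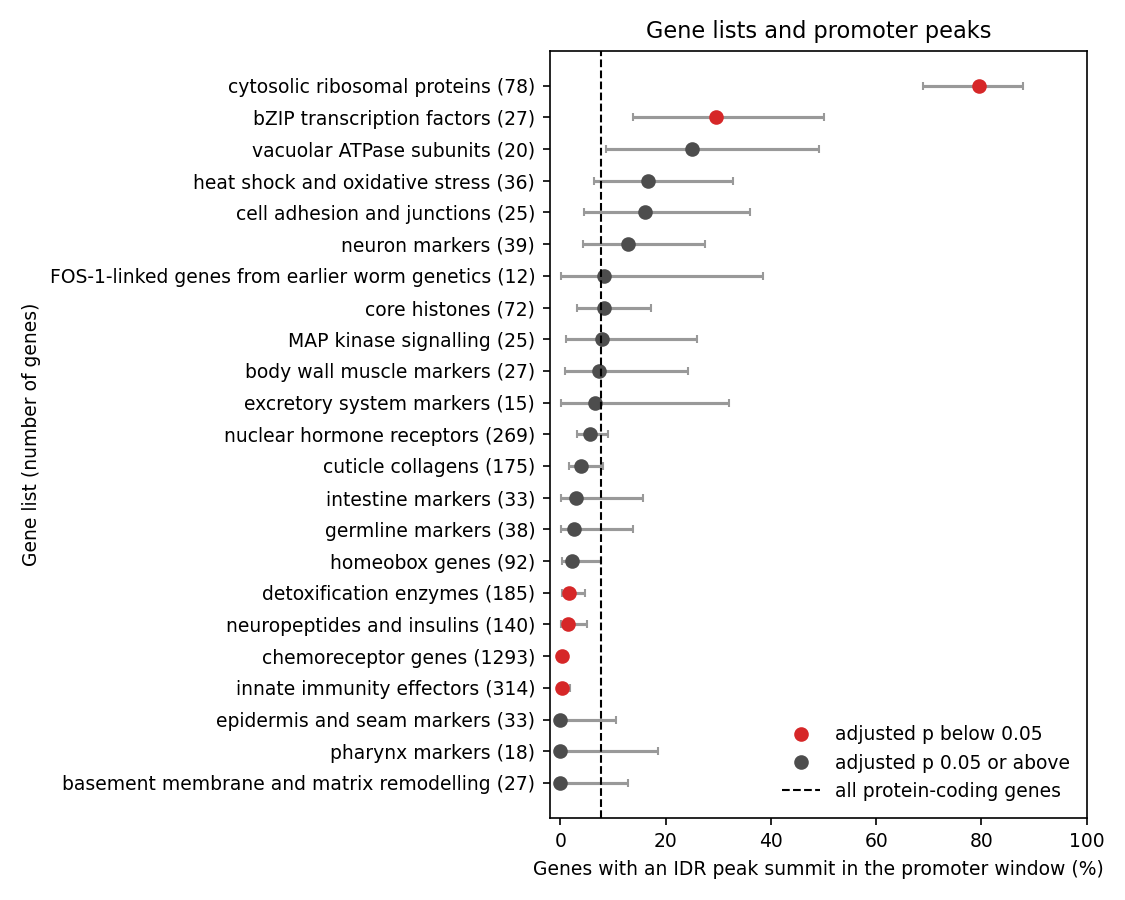
Percent of genes in each of 23 lists with an IDR summit in the promoter window (points, with 95% Clopper-Pearson intervals; list sizes in brackets; dashed line, 7.65% of all protein-coding genes). Ribosomal protein genes are at 79.5% and chemoreceptor genes at 0.387%.

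The X chromosome held 333 of the 1869 nuclear IDR peaks (17.8%, interval 16 to 20), close to its 17.7% of the nuclear genome (exact binomial test, two-sided, p = 0.856). It exceeded the 13.7% of protein-coding genes that lie on X (exact p = 5.01e-07). The replicates alone gave 18.2% and 17.1%. Among autosomes the density ran from 12.4 peaks per Mb on V to 24.8 on III, and X had 18.8. The small mitochondrial genome carried 26 peaks with a median signal of 277, against 61.7 on X. Neighbouring peaks are not independent, so these p-values are too small.

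Few regions were listed around fos-1 itself. The pooled list had 1 entry within 20 kb of the gene (V:6003601-6016087), where a window of that size held a median of 10, and 3.41% of windows had as few. Replicate 1 listed 1 entry and replicate 2 listed 2, against medians of 15 and 12, and none of the 3 lists had an entry in the gene body. By its name and the strain's unc-119 mutation, the transgene was presumed to carry an intact unc-119 as well. Around unc-119, the gene mutated in the strain's background (III:10902641-10908935), the pooled list had 9 entries, equal to the median of 9, of which 4 lay in the gene body. Around jun-1 (II:9113157-9132231) it had 28, a number reached by 1.85% of windows. Of these 3 genes, jun-1 was the one with an IDR summit in its promoter window. With 40 kb on each side, 18.8% of windows had as few pooled entries as fos-1.

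**Figure D4:**
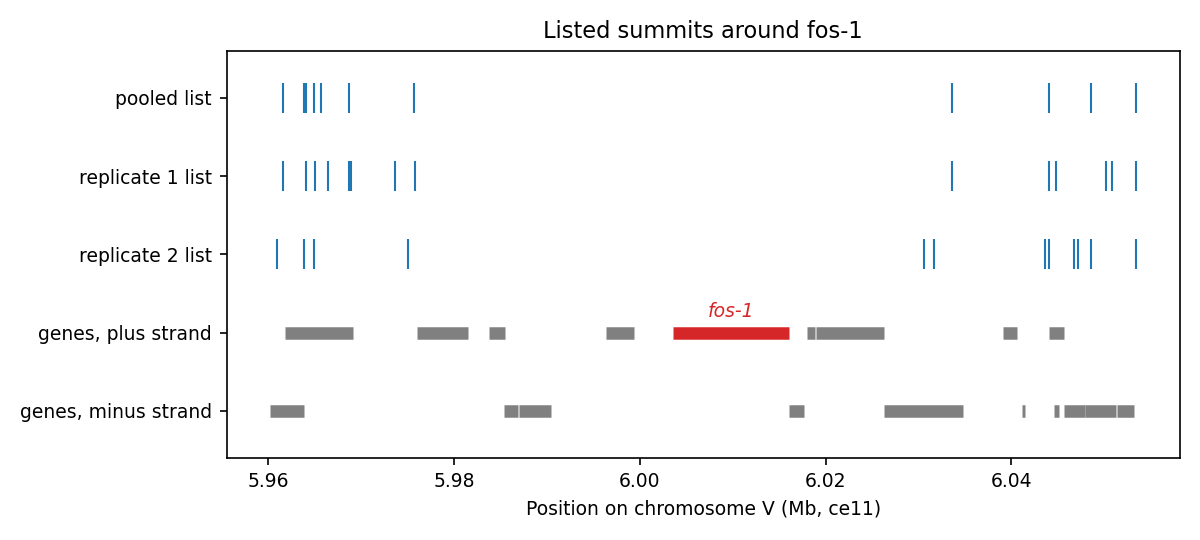
Summits of listed entries (blue ticks) in the pooled list and each replicate's list around fos-1 (red) on chromosome V in ce11, with protein-coding genes in grey by strand; the horizontal axis is position in Mb. No tick falls in the fos-1 gene body in any of the 3 lists.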

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

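Restricting to nuclear chromosomes and leaving out ribosomal protein genes were chosen after seeing the data; the other alternatives were planned. Under every alternative run, IDR peaks overlapped both replicate lists, top-ranked peaks overlapped between replicates, summits lay at promoters and AP-1 sites lay at summits more often than in the comparison sets, past the same thresholds. The IDR list was built from the replicate lists, so its overlap with them says little under any alternative. Counts of gene lists that passed ran from 5 to 8. Depth is unknown, so which weak sites went unlisted cannot be judged. The planned trend with the q column was not run, because that column is tied in all IDR peaks. No paired analysis was possible because there is 1 group. The cause of the changes below was not tested.

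In the 947 peaks of higher signal, the rank correlation between replicates was 0.639, and X held 17.2% of nuclear peaks, below its share of the genome. Each replicate alone gave 17.1% to 18.2% on X, and against its share of genes the 17.8% on X passed the test. The AP-1 trend within 100 bp had a rho of 0.0011, of opposite sign and near 0 both ways. The windows with as few pooled entries as around fos-1 were 3.79% with 10 kb and 18.8% with 40 kb each side, and 1.63% and 2.02% in the lists of replicates 1 and 2. For unc-119 they were 78.4% in replicate 2.

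The other changes of direction were all in comparisons that passed no threshold in either setting. TCASTGA was above its flanks at 2.90% within 100 bp, 0.844% within 25 bp, 4.91% in whole intervals and 1.48% in the 947 peaks, and was at 1.06% to 1.64% in each replicate alone. TGTTTAC was below its flanks at 1.37% in the 947 peaks. Among gene lists, the narrower promoter window turned MAP kinases (4.0%), body wall muscle (7.41%) and excretory markers (6.67%), and the wider one FOS-1-linked genes (8.33%) and histones (9.72%). Nearest genes turned heat shock (5.56%), histones (5.56%), nuclear hormone receptors (7.43%) and body wall muscle (7.41%). The background of named genes turned FOS-1-linked genes (8.33%), MAP kinases (8.0%) and histones (8.33%). Clusters of 5' ends turned body wall muscle (7.41%) and excretory markers (6.67%), and leaving out ribosomal protein genes body wall muscle (7.41%). The 947 peaks turned MAP kinases (4.0%), adhesion genes (4.0%), histones (1.39%), neuron markers (2.56%) and excretory markers (6.67%). Each replicate alone gave 4.0% to 8.0% for MAP kinases, 4.0% to 16% for adhesion genes, 5.56% to 8.33% for histones and 7.41% for body wall muscle. Of the 20 list members with a promoter peak named by the fixed rule, 14 had one among the 947 peaks, 18 in the top entries of replicate 1 alone, 16 in those of replicate 2 alone and 16 with the narrower promoter window, which lost cebp-1, kgb-1, sre-23 and ins-39.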

Other observations

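The sets of non-coding genes, the motif GCGCAGGG and all 3 patterns below were chosen after seeing the data; of the tests, those on tRNA and rRNA genes, on CGCAGGG, on other orders and genomic copies of GCGCAGGG, on windows with as many genes as around fos-1, and on the control file were also chosen only then. Classes of short non-coding genes held many peaks. Of 1869 nuclear IDR summits, 5.40% (interval 4.42 to 6.53) lay within 100 bp of a tRNA gene, 63 (3.37%) near a snoRNA gene and 23 (1.23%) near a snRNA gene. Shifted placements reached at most 0.589%, 0.482% and 0.268% (two-sided permutation, adjusted p = 0.0032 for each of the 3 classes among 8, from the smallest p that 1000 shifts can give, 0.0020). Counted by gene, 107 of 612 tRNA genes (17.5%), 63 of 346 snoRNA genes (18.2%) and 19 of 129 snRNA genes (14.7%) had a summit. Long intergenic RNA (lincRNA) genes were above the mean of shifted placements but not above their highest (0.803%, and 0.641% in each replicate alone, against a mean of 0.275% and a maximum of 0.856%; permutation adjusted p = 0.00533), while piRNA genes (0.268% against 2.10%, adjusted p = 0.0032) and pseudogenes (0.375% against 3.28%, adjusted p = 0.0032) were below. In the same permutation test, miRNA genes (0.161%, adjusted p = 0.384) and nuclear rRNA genes (0 of 20, adjusted p = 1.0) did not pass. The top entries of the replicates gave 5.24% and 5.02% for tRNA genes, 3.26% in each for snoRNA genes and a mean of 1.15% for snRNA genes.

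Among peaks with an AP-1 site, chosen after their values were seen, those at promoters included nhr-50, a nuclear hormone receptor gene (signal 144, 18 bp from the 5' end), act-2, an actin gene (141, 434 bp), gex-3, of the actin-regulating WAVE complex (97.5, 50 bp), and unc-112, a kindlin of muscle attachments (88.8, 333 bp). Besides cebp-1, higher promoter peaks with the site lay at F20D1.3 (signal 249), M04F3.4 (194) and Y18D10A.4 (146). Others, such as did-2 (133), rib-2 (116), uri-1 (116) and tag-77 (115), lay between those named. No shared function of these genes was tested. The stress list did not pass (6 of 36, Fisher's exact adjusted p = 0.137; 5.56% with nearest genes, below other genes); its 6 members with a peak, also named after their values were seen, were the heat shock genes hsp-110 (signal 207), hsp-1 (178), hsp-3 (168), hsp-60 (156), sip-1 (69.5) and hsp-6 (45.2).

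The peaks at ribosomal protein promoters were weighed first. They comprise 59 separate peaks, of which 0% held TGASTCA within 50 bp of the summit (upper 95% limit 6.06%). This argues against direct binding at that exact site as their source. The share over all IDR peaks was only 3.80%, so lacking the site does not set these peaks apart. The general pull-down of heavily transcribed loci remains a candidate explanation, but transcription was not measured here. Counted by gene, 17.5% of tRNA genes had a summit within 100 bp, against 79.5% of ribosomal protein genes in the promoter window. The tRNA genes, read by another polymerase, still held 5.40% of nuclear summits, above every shifted placement. Nuclear rRNA genes go the other way, with a summit at 0 of 20 (upper limit 16.8%), but 31.6% of the 31-base words in and around them occur once in the genome, against 77.4% for tRNA genes, so peaks there may go unlisted and this does not decide. Chromatin open at these loci for any factor was not separated from this, since no other factor or mock immunoprecipitation was used here, and with a single group no biological explanation was tested.

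Peaks on X with GCGCAGGG, the core of a motif known from X-linked recruitment sites of the dosage compensation complex, were weighed next. The octamer was within 50 bp of 14 of 333 X summits (4.20%, interval 2.32 to 6.95) and of 0 of 1536 autosomal ones. The 14 include a pair of summits in the same interval, X:2996953-2997349. The peaks with the octamer had a median signal of 223, and 3 of the 14 were at promoters. The highest had their nearest 5' ends at W02H3.3 (signal 396, 4018 bp away), Y41G9A.17 (350, 2648 bp), cest-16 (336, 3354 bp) and xol-1 (321, 4950 bp). The promoter peak of ins-39 named above (signal 192) is also among the 14. The shorter CGCAGGG, seen at the same time, was at 17 X (5.11%) and 15 autosomal summits (0.977%). The 167 other orders of the same 8 bases were each at 1.2% of X summits at most (95th percentile 0.901%). As the octamer was chosen after its summit counts were seen, this is not independent evidence against base composition around the peaks. Direct binding at TGASTCA is argued against, as 0% of the peaks with GCGCAGGG held it (upper limit 23.2%). Most IDR peaks lack that site too (3.80% held it). As for more copies on X, it holds 81 of 314 nuclear copies of the octamer (25.8%, interval 21 to 31). The density is 4.57 per Mb on X against 2.82 on autosomes. All 15 copies at summits lie on X (lower limit 78.2%). These summit counts had been seen when the octamer was chosen, so they are not independent evidence against more copies on X. CGCAGGG is about as dense on X (17 copies per Mb) as on autosomes (16). At summits lay 18 of its 301 copies on X and 15 of its 1329 autosomal copies. Whether these sites depend on FOS-1 was not tested, and with a single group no biological explanation was tested.

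The stretch without entries over fos-1 was weighed last. It ran from V:5975756 to V:6033637 in the pooled list (57.9 kb; 57.8 kb and 55.5 kb in the replicates), where 37 of 20329 stretches between neighbouring summits were at least as long, itself included, and spans 9 protein-coding 5' ends, among them those of the proteasome gene rpt-2 and of aps-1. Repeated sequence is argued against, since 99.2% of its 31-base words occur once in the genome. Few genes are argued against too: the region with 20 kb on each side of fos-1 holds 9 protein-coding 5' ends, and of 808 non-overlapping windows of that size whose number was within 2 of this, 1.49% (interval 0.77 to 2.58) had as few pooled entries, against 6.92% of windows with more. Extra fos-1 copies in the control library stay open, since the 0 entries of the 3 lists in the fos-1 gene body are the pattern itself and coverage of the control was not used here, and with a single group no biological explanation was tested. Around unc-119, presumed to be on the same transgene, the pooled list had 9 entries, equal to the median. The strain of the control and the length of copied unc-119 sequence are unknown, so this does not decide.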
